A study of Erythranthe nudata with 6 samples.

How the data were processed

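RNA was sequenced from the replum with its attached ovules of Mimulus nudatus, also called Erythranthe nudata, a monkeyflower. The plants descended from crosses among plants of 1 inbred line, and 150 F2 plants had been screened to find homozygous wild-type and homozygous mutant individuals. Per the labels' protocols, 6 gynoecia were taken from each plant, the ovary walls were removed, all RNA integrity numbers were above 7.3, and strand-specific libraries were made from about 100 ng of total RNA. The 3 wild-type and 3 mutant libraries came from different plants, so the replicates are biological.

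The authors deposited 1 table of read counts per gene, with a column for each library, and the values are raw whole-number counts that had not been normalized. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.11b, Picard 2.25.6, SAMtools 1.12 and featureCounts 1.22.2 were used. Per the file headers, the counted alignments were sorted STAR alignments with duplicate reads marked. Whether marked duplicates or reads with several positions were counted, which strand setting was used and which genome build was aligned to are not given in the sources used here. These choices affect near-identical gene copies most, because reads shared between copies can be dropped or assigned to either. Counting duplicates can widen the spread of abundant genes. Each column was assigned to its sample through the library name in the labels. The table had 0 other columns of samples.

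Identifiers in the table begin with MgTOL and end in v5.0. Whether these gene models were made for Mimulus nudatus was not examined here. The table identifies genes by annotation identifiers only, and no gene name, position or sequence was used here. The 16 gene lists fixed before the data were examined (ovule and carpel identity, female gametophyte, seed coat, hormones, cell division, photosynthesis, pollen, anther, petal and stamen, vasculature, stress, seed storage and others) therefore could not be matched to 1 gene and were not tested. Markers of other tissues, such as pollen, could not be examined for the same reason. The planned count of changed genes along scaffolds was not run. The causal gene of the mutation is not named in the labels, so its transcript does not serve as a check of the genotypes.

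Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 20305 of the 28064 genes. The 7759 others included 2625 with 0 counts in all 6 libraries. Counts were scaled with trimmed mean of M-values (TMM) factors and tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest, genotype as the only term, two-sided). P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p below 0.05. Log2 fold changes are mutant over wild type, and their standard error is the fold change divided by the square root of the F statistic. Levels are read counts scaled to TMM-adjusted library sizes (CPM). Classes of fold size and of abundance, and the set of genes called in every fit that left out a library, were chosen after the data were seen. For a gene without counts in a genotype, the fold was bounded with 3 counts over the 3 libraries of that genotype, which equals 0.0271 CPM in the mutant and 0.0223 CPM in the wild type. Classes of fold size set any mean below this limit at the limit. Intervals are exact 95% intervals and, like the limits, cover counting error only. Total counts per library lay between 35487055 and 45149217, so 1 count corresponded to 0.0212 to 0.0303 CPM.

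A gene was called detected in 1 genotype only if each of its 3 libraries had at least 10 counts and each of the other 3 had 0. By the rule fixed before the data were examined for a table without gene names, the identifiers named are the 2 with the largest rise and the 2 with the largest fall among changed genes with a mean count of at least 50 in the higher genotype and no overlap between genotypes. Measures of whole libraries were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries.

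The test was checked on counts simulated for this comparison, with the real means, library sizes and dispersions and 200 changed genes among 19917 to 19948 tested, according to the run. It recovered 0% of genes changed 2-fold and 0% of those changed 4-fold, 86.0% of those changed 8-fold, 93.5% of those changed 16-fold and 99.0% of those changed 100-fold, with 0 to 10 false calls per run. At this spread between plants, a missing call is therefore no evidence that a gene was stable. The changed genes were drawn only from genes above a minimum mean level, so the recovered shares do not cover genes at low levels. Each run also held changes of 1 size only, while the real data mixed sizes, which alters the p-value that adjustment demands. In the real data the smallest absolute log2 fold change called was 1.34, which is under 4-fold. The 0% at 4-fold therefore does not carry over to the real test. Alternatives were other scalings (RLE, upper quartile, total counts), other count filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), a robust fit, a replicate block, other thresholds, removal of the 20 most abundant genes and removal of each library in turn. Exact tests and plots used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.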

Results

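Transcript levels were measured by RNA sequencing in the ovule-bearing tissue of open flowers, from 3 wild-type plants and 3 plants homozygous for a recessive mutation that gives carpel-like ovules. The series title calls the mutant Medusa and places its defect in integument identity and in the female gametophyte. The comparison asks which transcripts differ between the mutant and the wild-type replum with its ovules. Total counts were 37798867, 45149217 and 42632019 in wild-type replicates 1 to 3 and 41038769, 35487055 and 42009912 in mutant replicates 1 to 3. The mean depth did not differ between the genotypes beyond the spread of the libraries (exact permutation test, two-sided p = 0.5). Genes are given by the identifiers of the deposited table.

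Each mutant library had fewer expressed genes than any wild-type library. A level of at least 1 CPM (here read counts scaled to total counts, without TMM factors) was reached by 17983 ± 286 genes in the wild type and by 16959 ± 313 genes in the mutant (mean ± SD, n = 3 each). At least 10 counts were recorded for 20335 ± 35.4 and 19312 ± 303 genes. For both measures the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow, so neither could pass a threshold of 0.05. TMM factors averaged 1.08 in the wild type and 0.932 in the mutant, so scaling with them would lower wild-type levels and raise mutant levels. Genes at 1 CPM were not counted with that scaling. The 20 most abundant genes took 7.17% ± 1.38 of the counts in the wild type and 9.41% ± 0.910 in the mutant (SD, n = 3 each, exact permutation p = 0.2).

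The genotypes were separated along the first principal component of log2 CPM, which held 42.7% of the variance. The second component held 25.9% and set mutant replicate 1, at 148, apart from the other mutant libraries at -74.0 and -44.9. The Spearman correlation across the 20305 tested genes averaged 0.940 between wild-type libraries, 0.912 between mutant libraries and 0.882 between genotypes. Mutant replicate 1 correlated with the other mutant libraries at 0.889 and 0.907, while those correlated with each other at 0.939. Its values lay partly within the range between genotypes, 0.851 to 0.897. The biological coefficient of variation was 44.9% among wild-type plants and 62.1% among mutant plants. No pair of replicates was alike within counting noise, as a library entered again would be, with a chi-square per degree of freedom of at least 201. The labels give a separate plant for each library, and all 6 were kept.

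**Figure D1:**
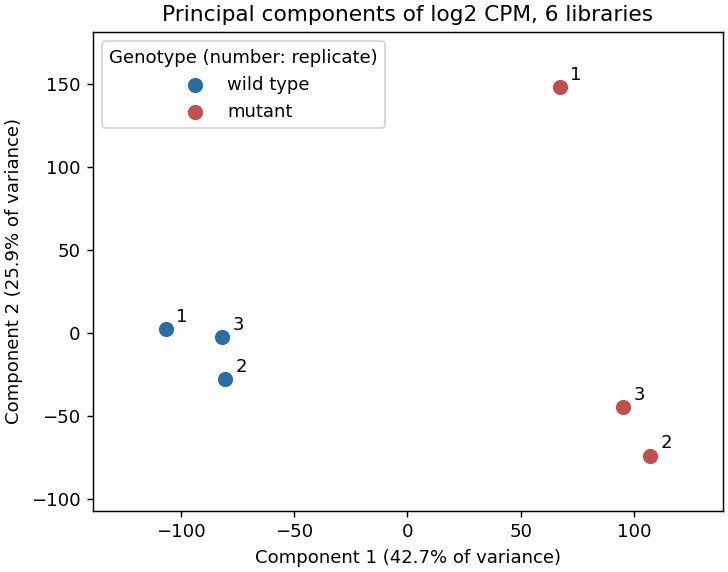
Principal components of log2 CPM over the tested genes, with 1 point per library and the replicate number beside it. The wild-type and mutant libraries lie at opposite ends of component 1, and mutant replicate 1 lies apart on component 2.

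Transcripts of a large set of genes fell in the mutant tissue and those of a smaller set rose. Of the 20305 genes, 309 (1.52%) changed (edgeR quasi-likelihood test, adjusted p below 0.05). Levels fell in the mutant for 246 of them, which is 79.6%, and rose for 63. None of the 309 overlapped between genotypes in any library, and the smallest absolute log2 fold change among them was 1.34. The median log2 fold change of all tested genes was 0.01. Without adjustment, 3007 genes had p below 0.05, against 1015 expected by chance, and they were nearly balanced, with 1458 higher and 1549 lower in the mutant. Ranges of the 2 genotypes did not overlap for 21.97% of tested genes, against 10% by chance. How far either expected value varies by chance, with genes that vary together, was not computed.

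The number of calls depended on every library. It was 62, 64 and 81 without wild-type replicates 1, 2 and 3, and 635, 146 and 77 without mutant replicates 1, 2 and 3. The 309 included 37 genes called in the fit of all libraries and in all 6 fits that left out a library, of which 36 fell and 1 rose, and this set was formed after the data were seen. DESeq2 called 1609 genes, with 643 higher and 966 lower, and all 309 were among them.

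**Figure D2:**
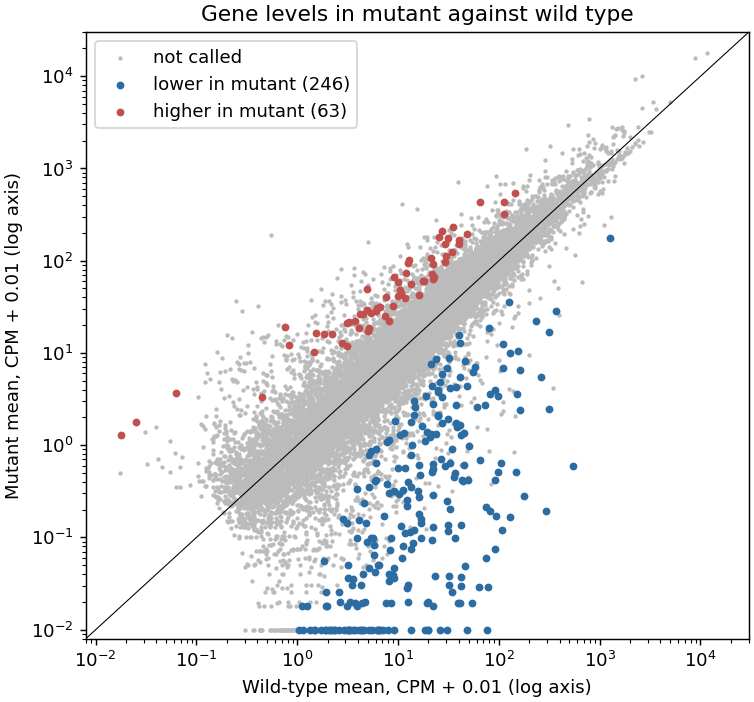
Mean CPM plus 0.01 of each tested gene in the wild type (horizontal, log axis) and in the mutant (vertical, log axis), with a line of equality. Blue points are the 246 genes called lower and red points the 63 called higher, and many blue points lie on the bottom edge, where the mutant mean is 0.

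The falls were deep. The 246 lower genes had a median level of 15.98 CPM in the wild type and 0.154 CPM in the mutant. With mutant levels below the counting limit set at that limit, 209 of them fell at least 10-fold, 106 at least 100-fold and 17 at least 1000-fold, and the median fall was 75.7-fold. The mutant mean was below 1 CPM for 180 of them and at least 10 CPM for 10. In the mutant, 42 of the 246 had 0 counts in all libraries and 41 had 1 to 3 counts in total. Together the 246 genes took 1.11% ± 0.344 of the wild-type counts and 0.0539% ± 0.0008 of the mutant counts (SD, n = 3 each), a difference on which they were chosen. Their share was 1.49%, 1.04% and 0.812% in wild-type replicates 1, 2 and 3. In the wild type, 153 of the lower genes exceeded a mean of 10 CPM and 21 exceeded 100 CPM. Among the 1000 most abundant wild-type genes, 9 fell and 0 rose at the adjusted threshold. Of all 20305 tested genes, 246 fell and 63 rose. The 1000 genes were picked for a high wild-type level, which favours falls over rises.

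The largest falls among genes that met the naming rule were in MgTOL.F1280.v5.0 and MgTOL.B0573.v5.0, whose functions are not given in the sources used here. MgTOL.F1280.v5.0 had 75.5 ± 30.8 CPM in the wild type (SD, n = 3), with 4279, 1894 and 3872 counts, and 0 counts in every mutant library. It was at least 2782-fold lower, with 3 counts over the mutant libraries as the limit (edgeR adjusted p = 0.0072), and its adjusted p stayed at or below 0.042 in all 16 alternative fits. Without mutant replicate 3 the bound was 1738-fold, as fewer mutant counts raise the limit. MgTOL.B0573.v5.0 had 48.4 ± 42.8 CPM in the wild type, with 4293, 688 and 1467 counts, and 0 counts in every mutant library. It was at least 1784-fold lower (edgeR adjusted p = 0.027), a bound that became 903-fold without wild-type replicate 1 and 1111-fold without mutant replicate 3. Its adjusted p was 0.055 without wild-type replicate 1, 0.095 without wild-type replicate 3, 0.058 without mutant replicate 2, 0.070 without mutant replicate 3 and 0.088 with limma-voom. Over all its alternatives the adjusted p ranged from 1.55e-18 with DESeq2 to 0.095.

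The rises were smaller. The 63 higher genes had a median level of 9.87 CPM in the wild type and 43.0 CPM in the mutant, with a median rise of 4.97-fold. The rise was at least 4-fold for 43 of them, at least 10-fold for 7 and at least 100-fold for 0, with wild-type levels below the counting limit set at that limit. Most were already expressed in the wild type, where 31 had a mean of at least 10 CPM, 26 had 1 to 10 CPM and 6 had less than 1 CPM. In the mutant, 16 exceeded 100 CPM. They took 0.128% ± 0.0151 of the wild-type counts and 0.496% ± 0.0552 of the mutant counts (SD, n = 3 each), again the difference on which they were chosen. The number of higher calls was 2, 2 and 10 without wild-type replicates 1, 2 and 3. It was 231, 15 and 3 without mutant replicates 1, 2 and 3.

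The largest rises among genes that met the naming rule were in MgTOL.D1011.v5.0 and MgTOL.L0389.v5.0, both nearly silent in the wild type. MgTOL.D1011.v5.0 had 1, 0 and 1 counts in the wild type and 81, 78 and 30 in the mutant, or 0.0153 ± 0.0132 against 1.78 ± 0.925 CPM (SD, n = 3 each). The ratio of pooled levels was 115, with a 95% counting interval of 31.4 to 957, and the log2 fold change was 6.63 (SE 1.06, edgeR adjusted p = 0.038). MgTOL.L0389.v5.0 had 2, 1 and 4 counts in the wild type and 118, 29 and 286 in the mutant, or 0.0532 ± 0.0368 against 3.67 ± 2.995 CPM (SD, n = 3 each). Its pooled ratio was 75.3, with an interval of 36.3 to 188, and the log2 fold change was 6.05 (SE 1.04, edgeR adjusted p = 0.044). This log2 fold change was 5.22 without mutant replicate 3 and 6.68 without wild-type replicate 3. Among the fits that left out a library, both calls were lost without any single wild-type replicate and without mutant replicate 3, and that of MgTOL.D1011.v5.0 also without mutant replicate 2. With limma-voom the adjusted p was 0.072 and 0.18. Neither gene passed the stricter count filter of at least 1 CPM in 3 libraries, so neither was tested there. Over the 15 other alternatives the adjusted p of MgTOL.D1011.v5.0 ranged from 1.8e-05 with DESeq2 to 0.15. That of MgTOL.L0389.v5.0 ranged from 3.03e-07 with DESeq2 to 0.198.

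**Figure D3:**
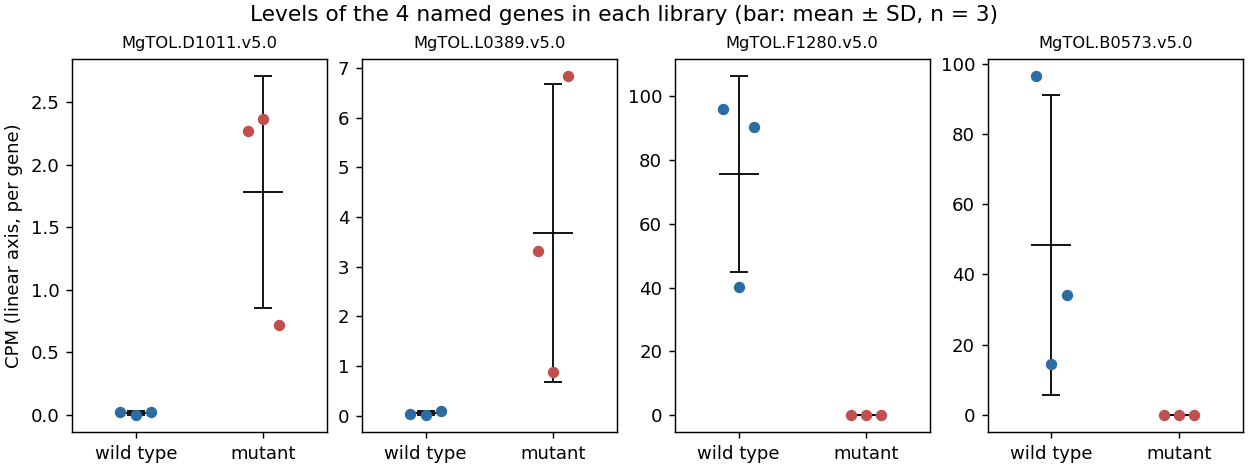
Levels of the 4 named genes in each library, in CPM on a linear axis that differs by gene. Points are libraries, and black bars give the mean and SD (n = 3). The first pair of genes is near 0 in the wild type, and the second pair is at 0 in all mutant libraries.

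Complete absence from 1 genotype was found in a single direction. At least 10 counts in each wild-type library and 0 in each mutant library were recorded for 94 genes, while 0 genes showed the reverse. Of these 94 genes, 91 passed the count filter and 42 were called lower in the test. Of those 42, 5 were also called in every fit that left out a library, as were 37 of all 309 called genes, a similar share. The wild-type mean of the 91 ranged from 0.290 to 75.5 CPM, with a median of 1.48 CPM. Their levels were at least 10.7-fold to at least 2782-fold lower in the mutant, with a median bound of 54.6-fold. In total the 94 genes took 27719, 17277 and 15905 counts in wild-type replicates 1, 2 and 3, which is 0.0733%, 0.0383% and 0.0373% of each library. They came from 14 of the 15 letter series of identifiers, with at most 16 in a series.

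The count of genes seen only in the wild type was 59 when 20 counts per library were required. When 1 count was tolerated in each library of the other genotype, it was 137, and 3 genes were then found in the mutant only. It was 170, 160 and 149 without mutant replicates 1, 2 and 3 and 113 to 124 without a wild-type replicate, and the reverse count then lay between 0 and 9, with the highest values without mutant replicate 1 and, at 8, without wild-type replicate 3. A count of 0 in a mutant library leaves room for levels up to 0.0717 to 0.0909 CPM.

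**Figure D4:**
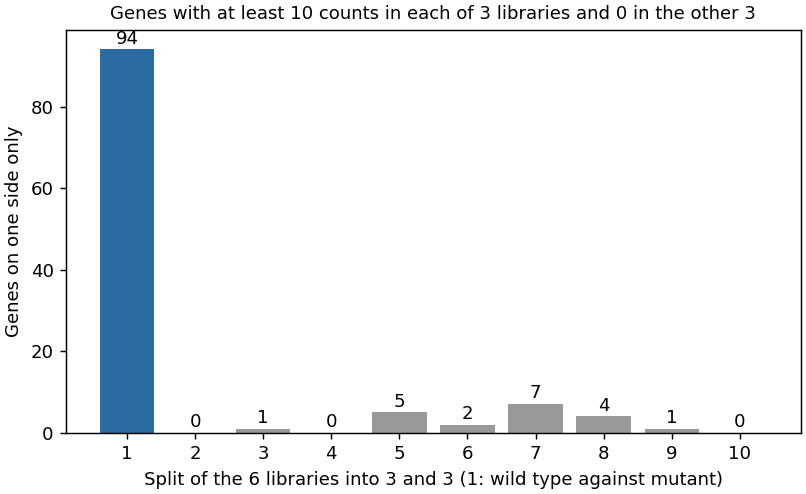
Number of genes with at least 10 counts in each of 3 libraries and 0 in the other 3, for each of the 10 ways to divide the 6 libraries. The division by genotype gives 94 genes, and the others, which mix the genotypes on both sides, give 0 to 7.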

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

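Removal of single libraries for the counts of genes seen in 1 genotype only, and for the bounds of the named genes at 0 counts, was chosen after the results had been seen. Of the 309 changed genes (63 higher, 246 lower), 283 to 305 were also called with RLE, upper-quartile or total-count scaling, which gave 306 to 323 calls. Total counts alone moved the median log2 fold change to -0.19 and left 38 genes higher. Without a count filter there were 325 calls, with the stricter filter 314, with the robust fit 301, without the 20 most abundant genes 305, and with limma-voom 237. DESeq2 gave 1609 (643 higher, 966 lower, 1516 at least 2-fold); the cause was not tested. An adjusted p below 0.01 left 47 (2 higher, 45 lower, all at least 2-fold), and one below 0.1 gave 693 (190 higher, 503 lower, 691 at least 2-fold). Testing against a 2-fold threshold with glmTreat left 165. Leaving out 1 library gave 62 to 635 calls, 2 to 231 higher and 60 to 404 lower, all at least 2-fold, and kept 58 to 283 of the 309 with no change of sign. Fewer libraries leave fewer degrees of freedom, yet the 635 came without mutant replicate 1. With a replicate block 103 genes were called (15 higher, 88 lower, all at least 2-fold), 93 of them among the 309, and the adjusted p was 0.125 for MgTOL.D1011.v5.0 and 0.057 for MgTOL.L0389.v5.0. The numbers are not known to pair the plants. Deviations of same-numbered libraries correlated at 0.094, 0.197 and -0.027 for replicates 1, 2 and 3. The values of replicates 1 and 2 were the highest of all pairs, as pairs with unlike numbers lay between -0.152 and 0.045. Wild-type replicate 3 correlated better with mutant replicate 1 (0.045) than with mutant replicate 3 (-0.027). Whether same-numbered plants shared a batch therefore stays open. Wild-type-only genes numbered 59 at 20 counts and 113 to 170 with 1 library left out. Mutant-only genes numbered 3 when 1 count was tolerated and 0 to 9 with 1 library left out. For the 4 named genes no alternative reversed the sign, and 18 of 62 fits left the adjusted p at 0.05 or more, 0 of them for MgTOL.F1280.v5.0. With the stricter filter MgTOL.D1011.v5.0 and MgTOL.L0389.v5.0 were not tested. The gene list tests and windows along scaffolds were not run, as names and positions were not used. Depth limits the lowest levels, since 0 counts in a library allow up to 0.0635 to 0.0909 CPM.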

Other observations

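Wild-type plants differed among themselves in the genes that were at 0 counts in the mutant. Of the 91 tested genes seen only in the wild type, 51 were highest in wild-type replicate 1, 25 in replicate 2 and 15 in replicate 3. Their median deviation in replicate 1 from the mean of the other wild-type libraries was 0.63 on the log2 scale. The median of 10000 random gene sets matched on wild-type level was 0.12, and 95% of them lay between -0.06 and 0.30. These sets were drawn gene by gene, so the interval takes no account of genes that vary together and may be too narrow. Each replicate was 1 plant, and no matched sets were counted for the 51, 25 and 15 genes.

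The tests of depth, of a single source, of a wrong label, of wild-type tissue, of the scaling as a cause, of neighbouring genes and of splits for genes seen in 1 group only were chosen after the results they bear on had been seen, while the splits for edgeR calls and the alternative fits quoted were planned. The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. For all changed genes, those at least 2-fold, those higher and those lower, 1 split, the real one, gave a count as large, with 309, 309, 63 and 246 genes, while the highest of the other splits gave 0. For genes seen in 1 group only, 1 split, the real one, gave 94, and the highest other gave 7. Every other split puts both genotypes into each group, which widens the spread within groups, so few calls were expected there. Likewise, genes read in 1 genotype and absent from the other cannot meet the rule in such a split.

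The pattern with the clearest direction was the 94 genes read in the wild type and at 0 in the mutant. A lower depth of the mutant libraries is argued against, because 84 such genes and 1 in the reverse direction were found after every library had been thinned to 35487055 counts. A single transcript source in 1 ratio, missing from the mutant, would shift the genes together between wild-type plants with no added spread, and they did shift together, but the SD of their deviations was 1.19, at the 96.85th percentile of the matched sets (median 0.937), so a single source and several cannot be told apart. A first form of this rule asked only for the joint shift and counted the values in favour of a single source, and the demand on the spread was added after that outcome was seen. Less transcript per cell in the mutant and a missing cell type both stay open, and neither was tested.

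Mutant replicate 1 stood apart, and the number of calls rose from 309 to 635 without it. A mislabelled library is argued against by 46 genes with at least 100 counts in every wild-type library and 0 in the other mutant libraries, whose median in mutant replicate 1 was 0.072% of the wild-type level. Wild-type tissue at a share of 1% or more is argued against by that median and by 20 of the 46 genes at 0 counts, although 15 exceeded 1% and the highest reached 143% (by the same measure 11 of 37 genes exceeded 1% in mutant replicate 2, the highest at 35.1%, and 4 of 28 in mutant replicate 3, the highest at 22.6%); a first form of the rule that also used the upper quartile (2.65%) had left this open and was replaced after its outcome was seen, so smaller or uneven admixture stays open. A lower depth of the library is argued against by its total of 41038769 counts, above the 35487055 of mutant replicate 2. A difference between mutant plants was not tested.

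More genes were called lower than higher, with 79.6% of calls lower. The share was 80.1% with RLE, 83.6% with upper-quartile and 88.2% with total-count scaling. A majority of lower calls was thus not particular to TMM among these scalings. The size of the share moved with the scaling, and higher calls went from 63 to 38 with total counts. None of these scalings raised the median log2 fold change, which was 0.014 with TMM, 0.012 with RLE, -0.082 with upper-quartile and -0.194 with total-count scaling. They could thus not lower the share, and a scaling error common to all of them stays open. The share was smaller with DESeq2 (60.04%), without mutant replicate 1 (63.6%) and at unadjusted p below 0.05 (51.5%). At 10-fold or more 209 calls were lower and 7 higher, and under 10-fold 37 were lower and 56 higher. Classes of fold size are set by the change itself, so these counts describe the calls and do not test why more of them were lower.

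Changed genes next to each other in the table were noticed first, and their pairs were then counted against random placements of the called genes. The p-values therefore describe this pattern and are no independent test that neighbouring rows change together. Neighbours were taken as consecutive tested genes within an identifier series. The 246 lower genes formed 14 adjacent pairs, against a mean of 2.86 and a maximum of 8 in 1000 placements (one-sided permutation p = 0.001, the smallest these can give). Within 5 rows they formed 45 pairs against a mean of 14.6 (one-sided permutation p = 0.001). The 63 higher genes formed 1 adjacent pair (one-sided permutation p = 0.174) and 4 pairs within 5 rows (one-sided permutation p = 0.014). These 4 tests were not adjusted for each other, nothing used here says that the order follows genome position, and reads shared between similar genes were not tested.

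At least 4-fold above every other library, at a mean of at least 1 CPM and with 0.5 CPM added, were 105 genes in mutant replicate 2 and 84 in mutant replicate 1, against 7 to 28 in the other libraries. At least 4-fold below every other library were 75 genes in mutant replicate 1 and 12 to 47 in the other libraries.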
